A study of Mus musculus with 6 samples.

How the data were processed

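RNA was extracted with TRIzol from Hepa1-6 cells stably transduced with shERO1A or shNC lentivirus and selected with puromycin, and sequenced as 3 libraries per group, per the labels. HISAT2 2.1.0, HTSeq 0.11.2 and the mm39 build are named in the submitters' processing notes. The gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of 16217 genes. Its FPKM columns, 1 per library, carry no unit in the deposited header; each was identified as FPKM from its values, since dividing by 1 length factor per gene gives whole reads and the value of 1 read in a library is inversely proportional to that library's total. Per the file headers, base means are a signal made by the authors with DESeq2 (version not given), as counts over size factors averaged over a group or over all libraries. Per the file headers, the table also holds the authors' fold change as a ratio, their log2 fold change, and their p-value and q-value. The lowest base mean over all libraries is 1.14, so genes with fewer reads are not among those analysed here.

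The columns of the shNC libraries match the titles of 3 samples by name. The columns KD1, KD2 and KD3 name the knockdown group but no single sample title, so they were used as 3 libraries of that group with no replicate number, and no library was paired with another.

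Reads per library were recovered from the FPKM values and the group base means: 100% of 97302 values came out within 0.01 of a whole number, and on 5000 simulated genes the same steps recovered 100% of the reads. The recovered totals were 38851690, 38290505 and 38514730 reads in shNC and 38387244, 38432822 and 39646829 in KD1, KD2 and KD3, counted over the genes of the table. They differ by little, so depth limits each library alike. Libraries of a group differed beyond sampling noise, with a chi-square per degree of freedom of 4.10 to 4.57 within shNC, 5.95 between KD1 and KD2, and 58.8 and 45.0 between KD3 and these, so no library was taken for a copy of another. Between groups, without KD3, it lay between 29.3 and 31.6.

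The design fixed before the data were examined assumed a table of counts. Because the deposited unit is FPKM, the test named there for such a unit was used. Genes with a mean of at least 1 FPKM over the 6 libraries were kept (10296 genes), log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with an intensity trend and no covariate, and p-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes; ratios are of mean FPKM. Lists of genes were fixed before the data were examined: oxidative protein folding, ER chaperones and ER-associated degradation, ATF4 and integrated stress response, hypoxia response, glycolysis, class I antigen presentation, interferon-stimulated genes, chemokines and cytokines, immune checkpoint and co-stimulatory ligands, NF-kB targets, hepatocyte and fetal liver genes, cell cycle, p53 targets, NRF2 targets, matrix and mesenchymal genes, cholesterol synthesis, fatty acid synthesis, markers of immune cells, of fibroblasts and stellate cells and of endothelial cells, mitochondrially encoded mRNAs, and immediate early genes. Ero1a is in none. Of these 22 lists, 19 had at least 5 tested members and were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists. Older symbols in the table were matched by hand.

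The genes named in the text follow a rule set at the same time: Ero1a; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM (reads per 1e6 reads), no overlap of the groups and a named symbol that is no pseudogene; up to 4 called members of each list with the largest change and a mean of at least 1 CPM; and Cd274, Cxcl9, Cxcl10, Ccl5, H2-K1, H2-D1 and B2m whatever their test. Some genes that were picked this way or stood out in a list are not reported here. Other genes named were chosen after their values were seen: Oas3, Vegfa, Cd68, Ptprc, Pecam1, Malat1, and in the closing section Neat1, Afp, Apoa2, Apoe, Ambp, Igf2, Trf, Apob, Foxa2, Krt20, Cdh17 and Tspan8.

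The fit was tested on simulated data with 50 genes changed by each of 4 folds among 10276 tested genes: limma called 60% of changes of 1.25-fold, 98% of 1.5-fold and 100% of 2-fold and 4-fold, with 13 false calls among 192. The changed genes were drawn from those with a mean of at least 2 FPKM, so these rates do not cover lower genes. The spread of the simulated reads was taken from the shNC libraries alone and averaged over genes of similar level, so no gene had a spread of its own. No library as far from its group as KD3 was simulated, so these rates do not cover such a library. In simulated lists, camera called the 1 shifted list and none of 20 unchanged ones. The simulated genes varied independently, so this cannot show how often camera calls a list whose members vary together.

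Alternatives planned beforehand were voom in limma on the recovered reads with TMM factors, RLE and upper-quartile factors, no filter on low values, a filter of 1 CPM, leaving mitochondrial and abundant genes out of the scaling (genes over 1% of any library, of which there was 1), a pseudocount of 0.1, each library left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were the authors' deposited values, TMM factors, no intensity trend, and the removal of each library's trend on gene length by lowess with a span of 0.3. Reactome and KEGG terms, as listed in the authors' deposited table, were tested for enrichment by a one-sided Fisher's exact test among tested genes with a term, for terms of 10 to 300 such genes. Chromosomes were taken from a RefSeq gene table of the GRCm38.p6 assembly, matched for 99.7% of tested genes; since the authors name mm39, no coordinates are printed. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.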

Results

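Messenger RNA was measured in cells that the labels give as Hepa1-6, a mouse hepatoma line, after stable transduction with a lentivirus carrying a short hairpin RNA. In 3 libraries the hairpin was directed against Ero1a (shERO1A), and in 3 libraries it was the control hairpin shNC. The shERO1A libraries are called KD1, KD2 and KD3 here, after the deposited table. Ero1a encodes an oxidase of the endoplasmic reticulum that passes disulfide bonds to protein disulfide isomerases. The deposited table lists 16217 genes in FPKM, and between 38290505 and 39646829 reads per library lie behind its values. Of these genes, 10296 had a mean of at least 1 FPKM over the 6 libraries and were tested. Nothing in the labels says that the libraries came from separate cultures, so adjusted p-values here measure the spread between these libraries, which may be technical.

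The target itself was reduced in each knockdown library. Ero1a (Entrez 50527) stood at 37.8, 39.6 and 38.4 FPKM in shNC and at 15.0, 16.0 and 15.7 FPKM in shERO1A. The mean fell from 38.6 ± 0.937 to 15.6 ± 0.505 FPKM (SD, n = 3 per group), which left 40.3% of the control level (log2 fold change -1.26, SE 0.05, limma adjusted p = 6.21e-06). In this gene the 6 libraries followed their labels.

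The main comparison asked which genes differ between tumour cells with and without the knockdown, in a study whose title concerns T cell recruitment and PD-L1 blockade in liver cancer. Each line is 1 hairpin, so for every gene an effect of Ero1a loss cannot be told apart from other differences between the stable lines. In shERO1A, 976 genes were higher and 847 were lower at a limma adjusted p under 0.05, together 17.7% of the genes tested. Most of the changes were small. Of the called genes, 82.7% moved by less than 1.5-fold, and the median absolute log2 change was 0.34. On the log2(FPKM + 1) scale, 29 genes rose and 42 fell by 2-fold or more. That scale understates the change of low genes, and with a pseudocount of 0.1 the numbers were 59 and 79. The groups did not overlap in 40% of tested genes, where chance gives 10%. The numbers of calls depended on single libraries. Without shERO1A library KD3 they were 1515 higher and 1341 lower, and without KD2 they were 610 and 578. Leaving out shNC replicate 1, 2 or 3 gave 494, 488 or 497 higher genes and 482, 468 or 458 lower genes.

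**Figure D1:**
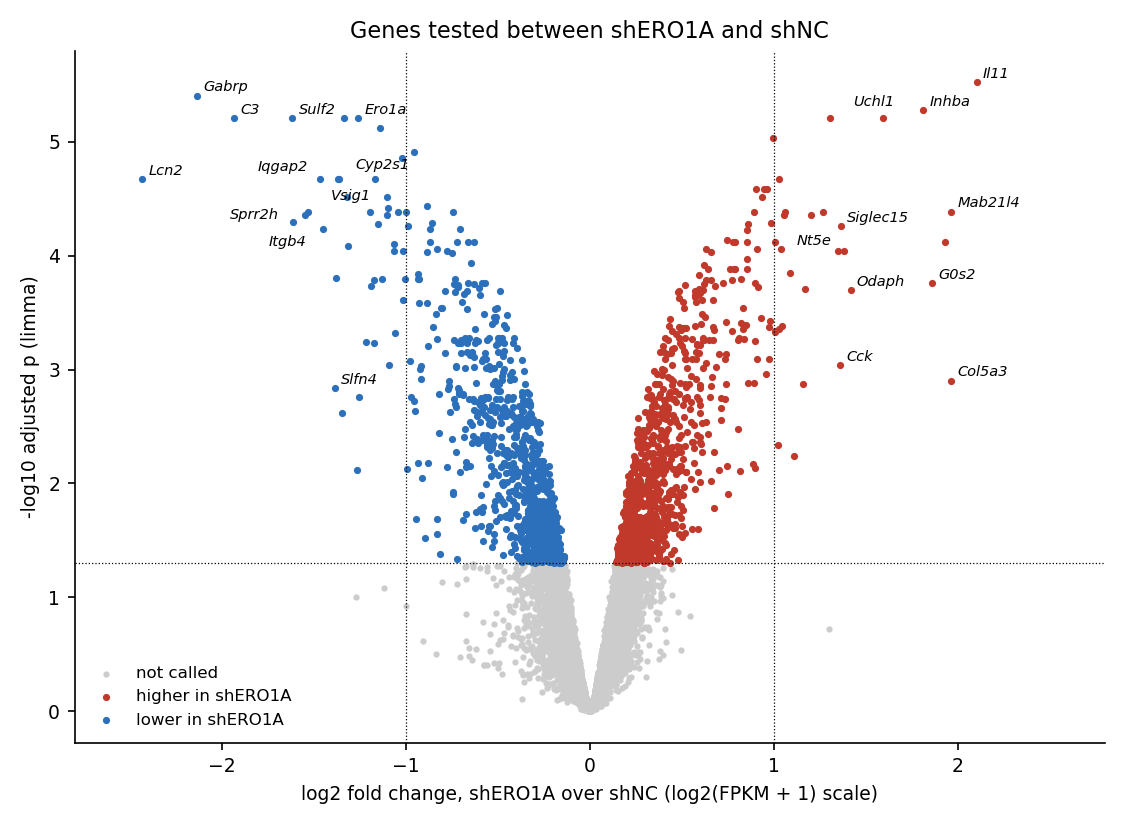
Log2 fold change of each tested gene (horizontal axis, shERO1A over shNC, log2(FPKM + 1) scale) against the negative log10 of its limma adjusted p (vertical axis). Red points mark the 976 genes higher in shERO1A, blue points the 847 lower, and dotted lines the adjusted p of 0.05 and changes of 2-fold. Ero1a and the 10 largest rises and falls of the named-gene rule carry their symbols.

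The largest rises included secreted signalling proteins. Il11, a cytokine that signals through gp130, rose from 5.13 ± 0.209 to 25.4 ± 0.934 FPKM (SD, n = 3), a ratio of 4.94. Inhba, the subunit of activin A, rose from 3.25 ± 0.133 to 13.9 ± 0.550 FPKM, and the gut hormone gene Cck from 2.79 ± 0.386 to 8.85 ± 2.15 FPKM. Nt5e, which encodes the adenosine-producing enzyme CD73, rose 3.43-fold, and Siglec15, a sialic acid-binding lectin, rose 3.60-fold. G0s2, an inhibitor of the lipase ATGL, rose 4.28-fold, and the deubiquitinase gene Uchl1 3.49-fold. Mab21l4 and Odaph rose 6.54-fold and 3.12-fold. Col5a3, a collagen chain, went from 0.385 ± 0.0374 to 4.63 ± 1.86 FPKM, with 5.72 and 5.69 FPKM in KD1 and KD2 and 2.49 FPKM in KD3. The limma adjusted p of these 10 genes lay between 3.01e-06 for Il11 and 0.00125 for Col5a3.

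The largest falls included genes of innate defence and of epithelial surfaces. Lcn2, which encodes the siderophore-binding protein lipocalin 2, fell from 23.8 ± 1.85 to 3.63 ± 0.742 FPKM (SD, n = 3). Complement C3 fell from 9.40 ± 0.236 to 1.72 ± 0.184 FPKM. Gabrp, a subunit of the GABA-A receptor, fell from 8.91 ± 0.296 to 1.26 ± 0.0674 FPKM. Sulf2, a sulfatase that edits heparan sulfate outside the cell, was at 0.274 of its control level. The integrin gene Itgb4 was at 0.332, the scaffold gene Iqgap2 at 0.269, the cytochrome gene Cyp2s1 at 0.332 and the adhesion gene Vsig1 at 0.376 of control. Sprr2h, a cornified envelope gene, was at 0.334 and Slfn4 at 0.255 of control; both belong to families of similar genes, so reads may be split between members. The adjusted p of these 10 genes ranged from 3.95e-06 for Gabrp to 0.00145 for Slfn4 (limma).

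Genes named by the theme of the study moved unequally. Cd274, which encodes PD-L1, rose from 2.74 ± 0.197 to 5.70 ± 0.636 FPKM (SD, n = 3), a ratio of 2.08 (limma adjusted p = 0.00054). The T cell chemokine Cxcl10 rose from 114 ± 2.27 to 164 ± 2.05 FPKM (adjusted p = 0.00018), and Ccl5 rose from 230 ± 6.40 to 386 ± 42.9 FPKM (adjusted p = 0.000804). Cxcl9 was hardly measured, with at most 0.0447 FPKM in any library, and was not tested. The class I heavy chain gene H2-K1 fell from 550 ± 9.81 to 479 ± 11.4 FPKM (log2 fold change -0.20, adjusted p = 0.032), a call lost with no filter on low values (adjusted p = 0.0572) and with any library but KD3 left out. Over 17 alternatives its adjusted p lay between 0.000416 and 0.152, the highest without shNC replicate 3. H2-D1 stood at 831 ± 16.0 and 800 ± 48.3 FPKM (adjusted p = 0.586), with a call without KD3 (log2 fold change -0.10, adjusted p = 0.028) and with the gene length trend removed (adjusted p = 0.0451), in a range from 0.028 to 0.869 over the alternatives. B2m, the light chain of class I, stood at 1836 ± 53.4 and 1898 ± 160 FPKM (adjusted p = 0.735). The class I heavy chain genes resemble each other, so their reads are uncertain.

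**Figure D2:**
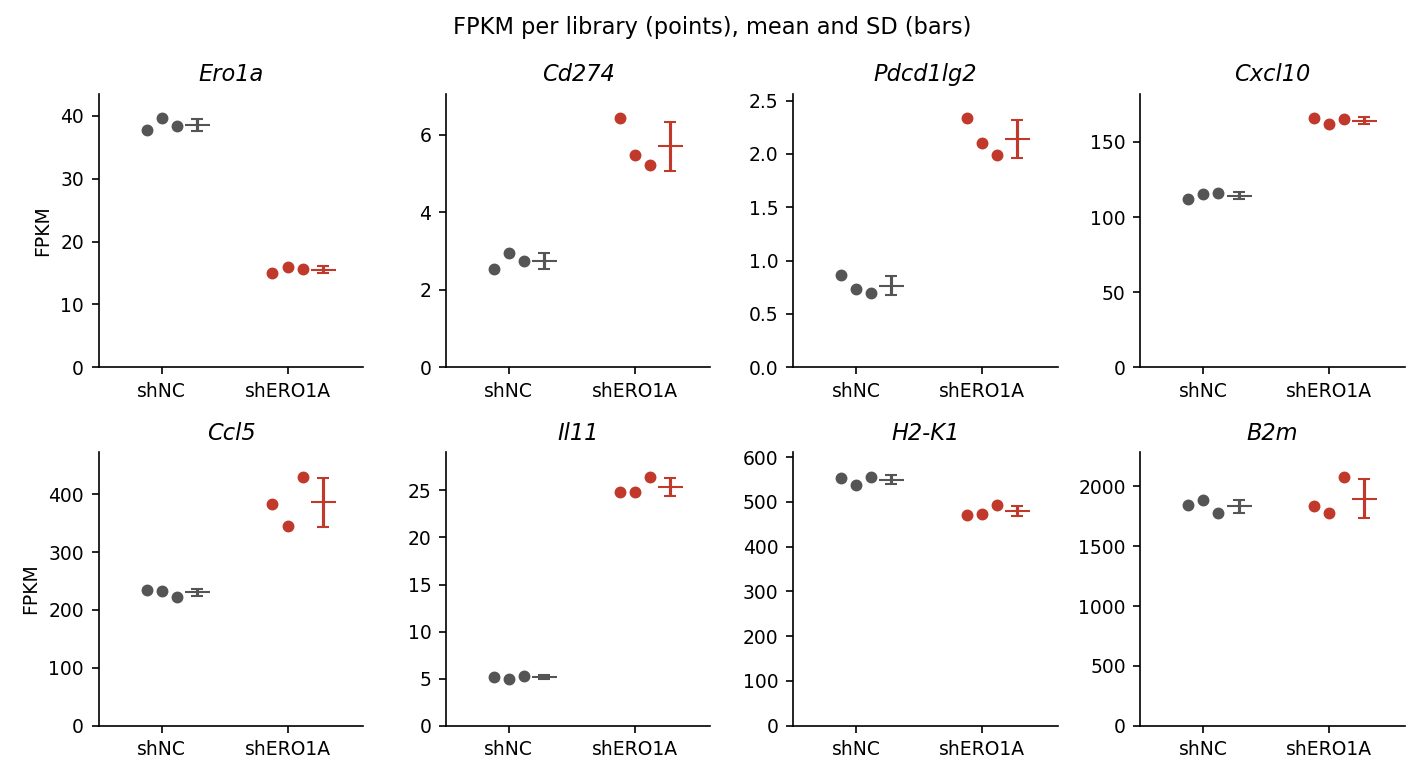
FPKM (vertical axes, starting at 0) of 8 genes in each of the 3 shNC libraries (grey) and the 3 shERO1A libraries (red), with the mean and SD beside the points. Ero1a lies near 15 to 16 FPKM in each shERO1A library, and Cd274, Pdcd1lg2, Cxcl10, Ccl5 and Il11 lie higher in all 3 shERO1A libraries than in any shNC library.

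Among chemokines and cytokines, changes went both ways. Of 22 tested members, 9 rose, 5 fell and 8 did not pass; adjusted over the list alone, the numbers were 11 and 6. Without KD3, 10 rose and 8 fell, and without shNC replicate 2 or 3 the falls numbered 3. Ccl4 rose from 0.984 ± 0.301 to 6.54 ± 0.747 FPKM (limma adjusted p = 7.66e-05), and Ccl8 from 2.23 ± 0.389 to 5.03 ± 1.27 FPKM. The neutrophil attractant Cxcl5 fell from 481 ± 8.85 to 263 ± 12.5 FPKM, and Csf3, the granulocyte growth factor, from 9.28 ± 0.739 to 4.35 ± 0.923 FPKM. As a set the list was not called by camera (adjusted p = 0.148), though it was called as higher with fry (adjusted p = 0.0347) and with the filter on reads (adjusted p = 0.0388). Of 12 immune checkpoint and co-stimulatory ligands, 4 rose and 3 fell, and 5 rose and 5 fell adjusted over the list alone. With any single library but KD3 left out, 3 rose and 2 fell. Besides Nt5e and Cd274, Pdcd1lg2 (PD-L2) rose from 0.764 ± 0.0912 to 2.14 ± 0.177 FPKM, while Vtcn1 (B7-H4) fell from 5.5 ± 0.226 to 2.42 ± 0.221 FPKM. This list was not called by camera either (adjusted p = 0.733), though it was called as higher with fry (adjusted p = 0.0155).

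Interferon-stimulated genes were the list with the most rises. Of 36 tested members, 20 rose, 1 fell and 15 did not pass, and adjusted over the list alone 24 rose and 2 fell. Rises numbered 14, 14 and 13 without shNC replicates 1, 2 and 3, and 25 without KD3. Usp18, which restrains interferon receptor signalling, rose from 131 ± 1.74 to 206 ± 18.0 FPKM (SD, n = 3). Ifit3 rose from 186 ± 4.94 to 282 ± 3.69 FPKM, and the guanylate-binding protein genes Gbp2 and Gbp7 rose 1.57-fold each. The single member that fell was Oas3 (log2 fold change -0.36); 2 fell without KD1 or KD3, and 0 without any single shNC replicate or KD2. The median log2 change of the list was 0.23 (camera adjusted p = 1.71e-07, and adjusted p = 0.0511 with an estimated correlation). In class I antigen presentation, 1 of 16 members rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.618). Without KD3, 3 rose and 3 fell, and without KD1 3 rose and 1 fell; 1 member was called without shNC replicate 1 or 2 or KD2, and 0 without shNC replicate 3. Psmb8, a subunit of the immunoproteasome, rose from 1.43 ± 0.316 to 2.25 ± 0.10 FPKM, and H2-Q4 fell from 51.5 ± 2.08 to 40.8 ± 3.21 FPKM together with H2-K1. The call of Psmb8 was lost with voom (adjusted p = 0.056), in the authors' deposited table (q = 0.109), without shNC replicate 1 or 3 (adjusted p = 0.0971 and 0.0961) and without KD2 (adjusted p = 0.0698), over a range from 0.0111 to 0.109. That of H2-Q4 was lost without shNC replicate 2 or 3 (adjusted p = 0.0589 and 0.0539; range from 0.000116 to 0.0589). Of 16 NF-kB targets none rose and 4 fell, and 1 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.136 with an estimated correlation). Without KD3, 2 rose and 6 fell, and without shNC replicate 3 only 2 fell. The adhesion gene Vcam1 fell from 11.9 ± 0.885 to 6.80 ± 0.689 FPKM, and Bcl3, Nfkbie and Zc3h12a were at 0.741, 0.762 and 0.851 of control. The call of Zc3h12a was lost without shNC replicate 1 or 3 (adjusted p = 0.0599 and 0.0515), with 0.00182 as the lowest over the alternatives. The call of Nfkbie was lost with no filter on low values (adjusted p = 0.0506), without shNC replicate 2 or 3 (adjusted p = 0.0944 and 0.0802), without KD1 (adjusted p = 0.0607) and without KD2 (adjusted p = 0.0613), with 0.0122 as the lowest over the alternatives.

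**Figure D3:**
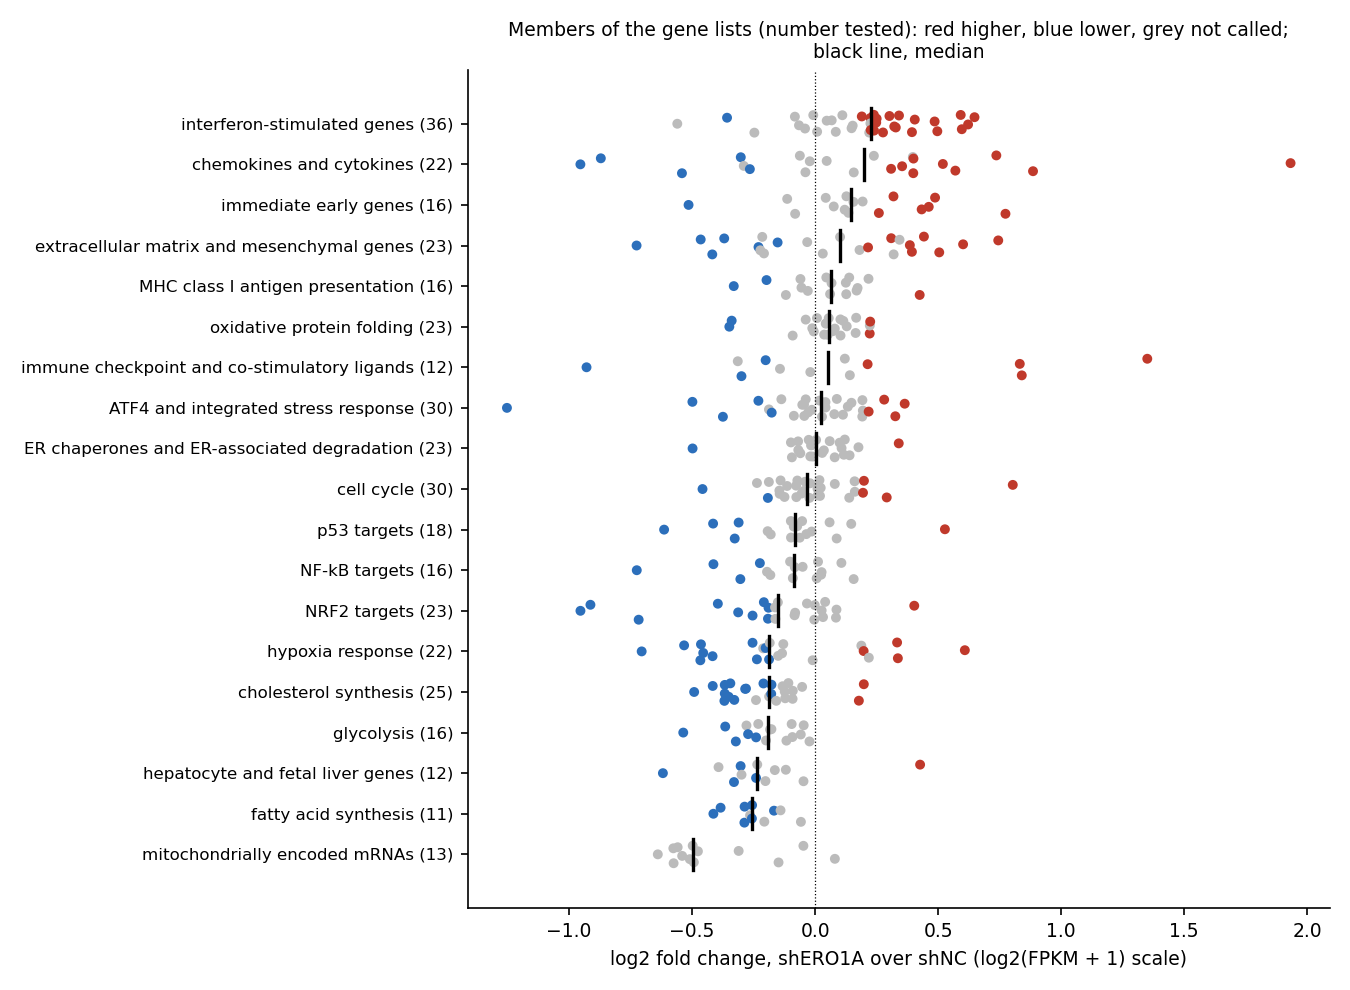
Log2 fold change of each tested member (horizontal axis, shERO1A over shNC, log2(FPKM + 1) scale) of the 19 gene lists with at least 5 tested members, ordered by their median (black line). Red points rose, blue points fell and grey points did not pass a limma adjusted p of 0.05 over all genes; interferon-stimulated genes have the highest median (0.226) and mitochondrially encoded mRNAs the lowest (-0.497), which is 0.00 without KD3.

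In oxidative protein folding, the machinery in which Ero1a works, 17.4% of the tested genes were called, where 17.7% were called over all genes. Of its 23 tested genes, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.367). Without KD3, 4 rose and 3 fell, and without KD1 4 rose and 2 fell. Without shNC replicate 1, 0 rose and 2 fell, and without shNC replicate 2, 0 rose and 1 fell. Without shNC replicate 3 or KD2, 1 rose and 2 fell. The paralog Ero1b fell from 2.27 ± 0.135 to 1.57 ± 0.0714 FPKM, and the sulfhydryl oxidase gene Qsox1 from 32.6 ± 0.723 to 25.6 ± 0.826 FPKM. Pdia4 and Tmx4, both of the disulfide isomerase family, rose 1.17-fold and 1.18-fold. Of 23 ER chaperones and degradation genes, 1 rose and 1 fell, with the same numbers over the list alone (camera adjusted p = 0.996). Without KD3, 3 rose and 2 fell, and without shNC replicate 1 or 3 there was 1 call. The 2 called genes were Dnajb9, from 11 ± 0.941 to 14.2 ± 1.16 FPKM, and Herpud1, from 75.9 ± 1.65 to 53.5 ± 2.92 FPKM. Some of these calls rested on single libraries. Ero1b lost its call without shNC replicate 2 (adjusted p = 0.0599), Pdia4 without shNC replicate 1 or 2 (adjusted p = 0.0613 and 0.0579) and Dnajb9 without shNC replicate 1 or 3 (adjusted p = 0.0723 and 0.0855). Tmx4 lost it without any single shNC replicate (adjusted p = 0.077, 0.075 and 0.118) and without KD2 (adjusted p = 0.0673). The lowest adjusted p over the alternatives was 0.000538, 0.000471, 0.0114 and 0.0152 for Ero1b, Pdia4, Dnajb9 and Tmx4. In the ATF4 and integrated stress response list, 4 of 30 members rose and 5 fell, and 8 rose and 7 fell adjusted over the list alone. Without KD3, 8 rose and 8 fell. Without shNC replicate 1 or 3, 1 rose and 3 fell, without shNC replicate 2, 3 rose and 3 fell, without KD2, 2 rose and 3 fell, and without KD1, 5 rose and 3 fell. Its median was 0.02 and its mean -0.02, with camera pointing down (adjusted p = 0.988). Stc2, a secreted glycoprotein, fell from 3.64 ± 0.941 to 0.936 ± 0.285 FPKM, Vldlr and Sesn2 were at 0.661 and 0.757 of control, and Atf3 rose 1.41-fold. The call of Atf3 was lost with voom (adjusted p = 0.056), with no filter on low values (adjusted p = 0.0659), in the authors' deposited table (q = 0.0592), without shNC replicate 1 or 3 (adjusted p = 0.119 and 0.118) and without KD2 (adjusted p = 0.0876), with 0.0279 as the lowest over the alternatives.

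Among genes of lipid synthesis, most calls were falls. Of 25 cholesterol synthesis genes, 13 fell, 2 rose and 10 did not pass, and 17 fell and 2 rose adjusted over the list alone. Without shNC replicates 1, 2 and 3, falls numbered 8, 8 and 9 and rises 0; without KD1, 14 fell and 1 rose, without KD2, 10 fell and 0 rose, and without KD3, 19 fell and 2 rose. Sqle, the squalene epoxidase, fell from 85.2 ± 0.686 to 65.8 ± 1.67 FPKM (SD, n = 3), Insig1 from 26.1 ± 0.938 to 18.2 ± 0.612 FPKM, and Lss and Cyp51 were at 0.730 and 0.770 of control. The median log2 change was -0.19 (camera adjusted p = 1.71e-07, and adjusted p = 0.0597 with an estimated correlation). Of 11 fatty acid synthesis genes, 7 fell and none rose, and 10 fell adjusted over the list alone; 4 fell without any single shNC replicate, and 10 without KD3. Scd2, a stearoyl-CoA desaturase, fell from 408 ± 9.23 to 313 ± 12.3 FPKM and Fads2 from 87.5 ± 1.89 to 65.5 ± 1.26 FPKM; Scd1 and Elovl6 were at 0.817 and 0.809 of control. The median was -0.26 (camera adjusted p = 1.84e-06, and adjusted p = 0.0597 with an estimated correlation).

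In the hypoxia, glycolysis and NRF2 lists, falls also outnumbered rises. In the hypoxia list, 10 of 22 members fell and 4 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.00829, and adjusted p = 0.0986 with an estimated correlation). Without shNC replicates 1, 2 and 3, falls numbered 6, 7 and 6 and rises 2, 2 and 3. Egln3, an oxygen-sensing hydroxylase, fell from 46.2 ± 0.686 to 28.0 ± 0.903 FPKM, Bnip3 from 64.5 ± 0.138 to 44.5 ± 5.34 FPKM and Pdk1 from 15.3 ± 0.112 to 10.8 ± 0.471 FPKM. Plin2, a lipid droplet coat protein gene, rose from 74.7 ± 1.66 to 114 ± 6.43 FPKM, and Vegfa rose as well (log2 fold change 0.33). Of 16 glycolysis genes, 5 fell and none rose, and 9 fell adjusted over the list alone; without KD3, 12 fell. Pfkp, Pfkl and Gpi1, all early glycolytic enzymes, were at 0.679, 0.771 and 0.799 of control, and the glucose transporter gene Slc2a1 was at 0.826 (camera adjusted p = 2.15e-05, and adjusted p = 0.0597 with an estimated correlation). Of 23 NRF2 targets, 9 fell and 1 rose, and 11 fell and 1 rose adjusted over the list alone; without KD3, 15 fell. Without shNC replicates 1, 2 and 3 and KD2, falls numbered 6, 5, 5 and 6 and rises 0. Ephx1, an epoxide hydrolase, fell from 110 ± 0.648 to 56.1 ± 1.18 FPKM, and Gclc, the catalytic subunit of glutathione synthesis, from 48.0 ± 1.24 to 28.9 ± 1.98 FPKM. Gsta4 was at 0.462 of control and Blvrb rose 1.36-fold (list: camera adjusted p = 0.000916, and adjusted p = 0.11 with an estimated correlation). Blvrb lost its call with no filter on low values (adjusted p = 0.0592), without any single shNC replicate (adjusted p = 0.0872, 0.0901 and 0.108) and without KD2 (adjusted p = 0.087), with 0.00346 as the lowest over the alternatives.

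Growth and matrix genes showed mixed changes. Of 30 cell cycle genes, 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.534); without KD3, 5 rose and 7 fell, without any single shNC replicate 2 rose and 0 fell, and without KD2 3 rose and 1 fell. Ccne1, cyclin E1, rose from 10.8 ± 0.355 to 19.6 ± 2.33 FPKM, E2f1 and Mcm6 rose 1.24-fold and 1.15-fold, and the proliferation marker Mki67 fell from 51.5 ± 1.67 to 37.6 ± 6.13 FPKM. Of 18 p53 targets, 1 rose and 4 fell, and 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.136 with an estimated correlation). The call of this list was also lost without shNC replicate 3 (adjusted p = 0.0509) and without KD1 (adjusted p = 0.0849), over a range from 0.00222 to 0.136. Without KD3, 2 of its members rose and 6 fell. Pmaip1 rose 1.51-fold, while Perp, Ccng1 and Ei24 were at 0.636, 0.749 and 0.795 of control. Of 16 immediate early genes, 6 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0105, and adjusted p = 0.103 with an estimated correlation). Rises numbered 2 and 3 without shNC replicates 1 and 3, and 2 members fell without KD3. Jun, Junb and Egr1 rose 1.81-fold, 1.41-fold and 1.44-fold, and Klf4 was at 0.688 of control. Of 23 matrix and mesenchymal genes, 8 rose and 6 fell, and 10 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.524). Falls numbered 3 without any single shNC replicate, and rises 5 without shNC replicate 2. Itga5 and Snai1 rose 1.53-fold and 1.6-fold, and the collagen cross-linking enzyme gene Loxl2 fell from 15.1 ± 0.521 to 8.75 ± 0.513 FPKM. Leaving out single libraries ended 4 further calls of this paragraph. Without any single shNC replicate these were Mki67 (adjusted p = 0.0749, 0.089 and 0.0985), Mcm6 (adjusted p = 0.0522, 0.0742 and 0.0636) and Ei24 (adjusted p = 0.0623, 0.0513 and 0.0758); Ei24 also lost its call without KD2 (adjusted p = 0.0532) and Mki67 with no filter on low values (adjusted p = 0.0555). Egr1 lost it with no filter on low values (adjusted p = 0.0508), without shNC replicate 1 or 3 (adjusted p = 0.0938 and 0.0798), without KD1 (adjusted p = 0.054) and without KD2 (adjusted p = 0.0767). The lowest adjusted p over the alternatives was 2.87e-05, 0.00144, 0.000157 and 0.000413 for Mki67, Mcm6, Ei24 and Egr1.

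Of 30 hepatocyte and fetal liver genes, 16 were analysed here and 12 tested, of which 4 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00483, and adjusted p = 0.0986 with an estimated correlation). Without shNC replicates 1, 2 and 3, falls numbered 1, 1 and 2 and rises 1, 0 and 0; without KD1, 2 fell, and without KD2, 1 fell. The liver transcription factor gene Hnf4a fell from 41.1 ± 1.12 to 33.2 ± 0.855 FPKM and Rbp4, the retinol carrier, from 341 ± 5.12 to 272 ± 29.2 FPKM. Hpx was at 0.612 of control and Apoh rose 1.38-fold. Of these, Rbp4 lost its call without any single library but KD3 (adjusted p up to 0.0964), Hpx without shNC replicate 1 or 2 (adjusted p = 0.0791 and 0.0736) or KD2 (adjusted p = 0.0548), and Apoh without shNC replicate 2 or 3 (adjusted p = 0.0692 and 0.0729). Their lowest adjusted p over the alternatives was 2.24e-05, 0.000342 and 0.00411. Of 16 markers of other cell types analysed here, 13 had a mean under 1 FPKM, and fewer than 5 members of each list reached the test. Of the immune markers, Cd68 was tested and did not pass, at 2.17 ± 0.213 and 2.63 ± 0.523 FPKM. Without KD3 it was called higher (log2 fold change 0.31). The leukocyte gene Ptprc did not exceed 0.0663 FPKM in any library. The pericyte marker Rgs5 rose from 1.3 ± 0.0630 to 3.28 ± 0.219 FPKM. The endothelial cadherin gene Cdh5 rose from 10.1 ± 0.448 to 18.3 ± 0.512 FPKM, while Pecam1 did not exceed 0.151 FPKM in any library.

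Library KD3 stood apart from the other libraries of its group. A principal component that held 62.8% of the variance separated the groups, and a further component with 22.4% separated KD3 from KD1 and KD2. The component with 62.8% also set KD3 (18.64) apart from KD1 (7.99) and KD2 (9.59), further from shNC. Mitochondrially encoded mRNAs took 0.568% of the reads in KD3 and between 1.65% and 2.0% in the other 5 libraries. None of the 13 mitochondrial mRNAs passed the test (limma; 1 had an unadjusted p under 0.05), none passed with voom (0 under 0.05 unadjusted), and none passed adjusted over the list alone (camera adjusted p = 0.0631). Without KD3, 1 passed, and without KD1, 2 passed, both lower. The call on the list changed when another shERO1A library was left out (adjusted p = 0.00153 without KD1 and 0.0393 without KD2), and without KD3 its median log2 change was 0.00. The nuclear RNA Malat1 was at 13.9 FPKM in KD3, against 50.7 and 47.2 FPKM in KD1 and KD2.

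Genes higher in shERO1A were unevenly spread over the chromosomes. By their Entrez identifiers, 10264 of the tested genes were placed on a chromosome with a gene table of the GRCm38.p6 assembly, which is not the build the authors name. On chromosome 6, 127 of 481 genes (26.4%) were higher and 24 were lower, where 8.7% of the genes on the other chromosomes were higher (Fisher's exact test over genes, two-sided, p = 2.19e-28, adjusted p = 4.38e-27 over 20 chromosomes; genes are not independent replicates). The median log2 change on chromosome 6 was 0.12, a rise of 8.7% in FPKM + 1, a scale that understates the change of low genes. This median was 0.12, 0.12 and 0.15 in KD1, KD2 and KD3 taken singly. No other chromosome had a median above 0.07, that of chromosome 8. Of the 20 interferon-stimulated genes that rose, 1 lies on chromosome 6.

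**Figure D4:**
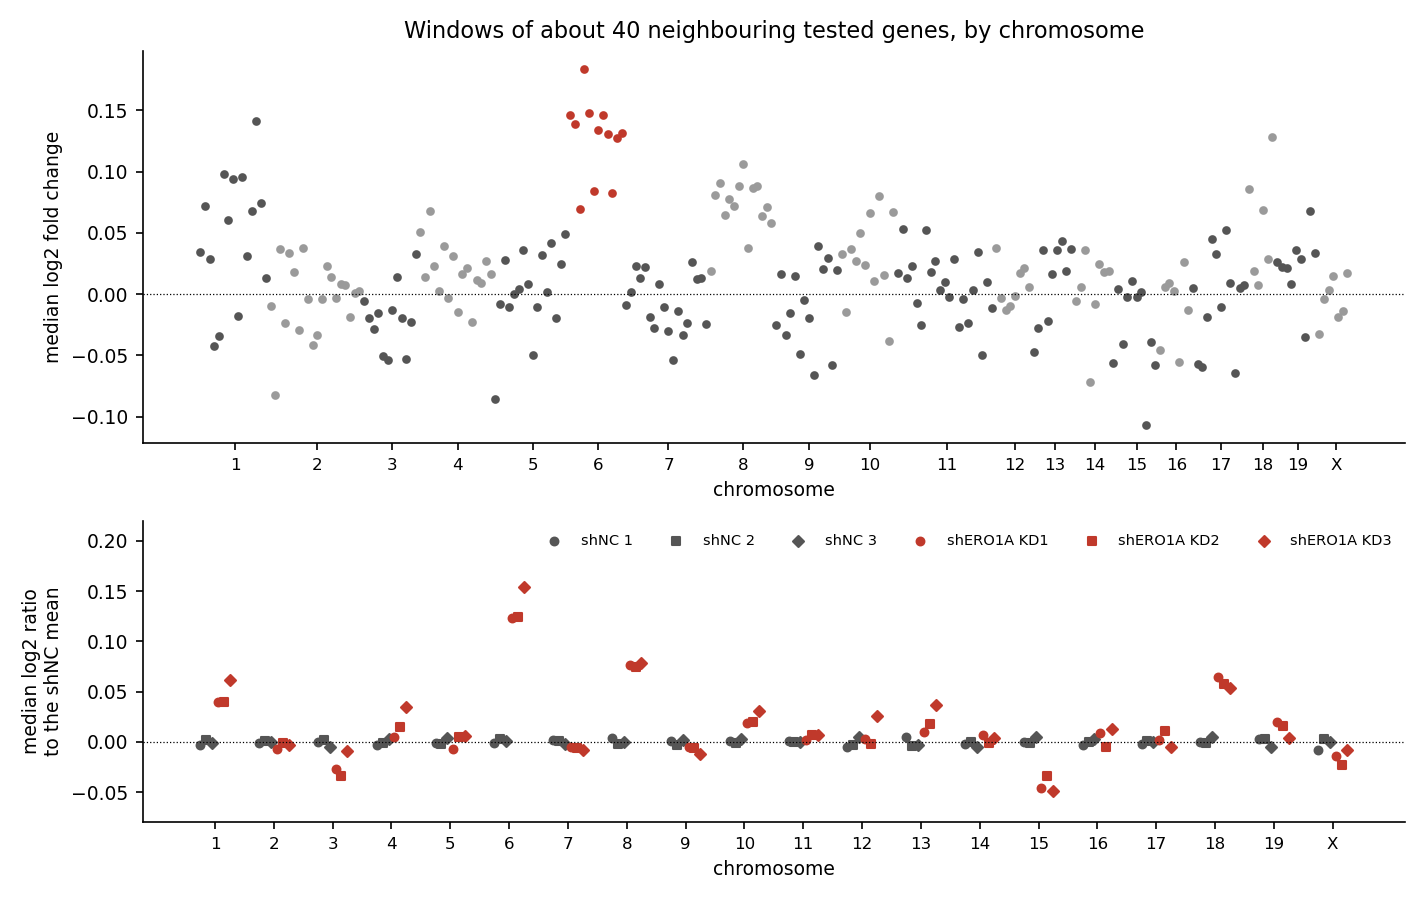
Above, the median log2 fold change (vertical axis, shERO1A over shNC) of windows of about 40 neighbouring tested genes, ordered along each chromosome (horizontal axis), with chromosome 6 in red. Below, the median log2 ratio of each chromosome's genes to the mean of the shNC libraries, for each shNC library (grey) and shERO1A library (red); chromosome 6 lies between 0.123 and 0.154 in the 3 shERO1A libraries.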

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

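Alternatives chosen only after seeing the data were the authors' deposited values, TMM factors, no intensity trend, the removed gene length trend and, for lists, the upper-quartile factors, the pseudocount of 0.1 and member counts with a library left out. Ero1a stayed lower and called in all 17 alternatives (log2 fold change -1.32 to -1.23, highest adjusted p 0.000242). No main call among the genes tested changed direction under any alternative. All alternatives reuse the same libraries, so a change of direction was unlikely from the start. The 21 genes made up of Ero1a and the 10 largest rises and falls were called under all 17, as were Cd274 (adjusted p at most 0.00527), Cxcl10 (at most 0.00319) and Ccl5 (at most 0.00813). Of 93 called genes picked by the naming rule, 75 stayed called throughout; 11 lost the call only with a library left out and 7 under other alternatives, as the report gives gene by gene. B2m was called under none. Fewer libraries lower the power, yet calls rose when KD3 was left out: with each library left out in turn, genes higher numbered 488 to 1515 and genes lower 458 to 1341. Of 1817 main calls tested without KD3, 1803 were called there too. Fewer were kept with any other library left out. These were 1422 of 1816 without KD1 and 1156 of 1815 without KD2. Without shNC replicates 1, 2 and 3 they were 959 of 1819, 942 of 1817 and 946 of 1818. The cause of the rise in calls without KD3 was not tested. Other settings gave 883 to 1123 genes higher and 812 to 1215 lower. Scaling factors moved the share of higher calls from 53.5% to 49.9% with RLE factors and 50.1% with TMM.

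Changes of 2-fold or more, 29 up and 42 down, numbered 63 and 86 with voom, 59 and 79 with a pseudocount of 0.1 and 157 and 203 in the authors' deposited table, whose folds carry no added pseudocount of 1 and which covers all 16217 genes. Gene lists called, 2 higher and 8 lower, fell to 0 higher and 0 lower with an estimated correlation, where 8 lists had an unadjusted p under 0.05 (camera); with fry, which does not compare a list with other genes, 4 were higher and 8 lower. Under the scalings, filters and left-out libraries, 2 or 3 lists were higher and 7 to 9 lower. No paired analysis was possible because the columns of the knockdown libraries carry no replicate number of the labels. Library totals are already the scaling of FPKM, and the count tests of the design were not run because the deposited unit is FPKM. In the simulation, which varied the fold but not the depth or the spread, the smallest changes were often missed (60% called).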

Other observations

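All tests in this part were chosen after the data were seen, except the count of other splits of the libraries. Among pathway terms of the authors' deposited table, those enriched among genes lower in shERO1A were led by Reactome's cholesterol biosynthesis, with 13 of 26 tested genes lower where 2.25 were expected by chance (one-sided Fisher's exact test over genes, adjusted p = 4.08e-05 over 854 terms). Formation of the cornified envelope followed, with 8 of 14 genes (adjusted p = 0.0016), a group of epithelial barrier genes, and extracellular matrix organization with 21 of 93 (adjusted p = 0.00631). A further 20 of these 93 genes were higher, which did not pass (adjusted p = 0.0507, and 0.0416 without KD3). KEGG's metabolism of xenobiotics by cytochrome P450 had 10 of 25 genes lower (adjusted p = 0.0057 over 300 terms) and bile secretion 11 of 30 (adjusted p = 0.0057). Cytokine-cytokine receptor interaction was enriched in both directions, with 21 of its 76 genes lower (adjusted p = 0.00253) and 19 higher (adjusted p = 0.0251). Among genes higher, no Reactome term passed (lowest adjusted p = 0.0507; 53 terms had an unadjusted p under 0.05), but 12 passed without KD3, among them hemostasis and the CDC42 GTPase cycle (adjusted p = 0.0325 each), and KEGG's cell adhesion molecules had 15 of 48 (adjusted p = 0.0159). The terms named above with an adjusted p under 0.05 kept it without KD3, except the rise of cytokine-cytokine receptor interaction (adjusted p = 0.0529).

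The labels give the cells as Hepa1-6, and the identity of the line was not tested here, a limit to keep in mind beside the levels that follow. The level of liver genes was low for some members in both groups. Afp was at 3.11 ± 0.0503 FPKM in shNC and 2.22 ± 0.871 FPKM in shERO1A (SD, n = 3), Apoe at 2.02 ± 0.454 and 1.68 ± 0.992 FPKM, and Apoa2 at 0.980 ± 0.0957 and 0.980 ± 0.138 FPKM. Ambp and Igf2 did not exceed 0.305 and 0.0229 FPKM in any library. Rbp4, Hnf4a, Trf, Apob, Foxa2 and Apoh were the 6 of the 16 liver genes analysed with a mean of at least 10 FPKM. Their means over all 6 libraries ran from 14.4 FPKM for Apoh to 307 FPKM for Rbp4. In the same libraries the intestinal cadherin gene Cdh17 was at 222 ± 1.97 FPKM in shNC and 228 ± 5.62 FPKM in shERO1A, the keratin gene Krt20 at 168 ± 2.51 and 187 ± 7.38 FPKM, and Tspan8 at 101 ± 1.89 and 70.0 ± 5.37 FPKM.

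In KD3 alone, most mitochondrial mRNAs and the nuclear RNAs Malat1 and Neat1 were low; these 2 were chosen after their values were seen, and no list of nuclear RNAs was tested. Of the 13 mitochondrial mRNAs, 11 were lower in KD3 than in both KD1 and KD2, with a median log2 ratio of -1.57, and Neat1 was at 3.72 FPKM against 16.9 and 16.3 FPKM. Over KD1 and KD2 the median log2 ratio of these mRNAs to shNC was 0.002, so the fall was not shared by the knockdown libraries. The pattern was picked as one of KD3 alone, so this value is no separate test of the knockdown. KD3 also held fewer reads of long genes (Spearman's rho -0.53 over 10002 coding genes, which are not independent replicates), but a loss of long RNA is argued against for the mitochondrial mRNAs, with a median of -1.784 log2 relative to nuclear mRNAs of the same length. An RNA preparation that kept less nuclear and mitochondrial RNA may be the source and stays open: 279 other non-coding genes had a median of -0.238 log2 relative to length-matched coding genes, between the bounds set for and against it, and 48.0% of them were lower in KD3 than in both KD1 and KD2, against 41.4% of coding genes.

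Genes on chromosome 6 may differ in copy number between the shERO1A and shNC lines, a hypothesis that cannot be told apart from a regulatory change, since each line is 1 hairpin and no DNA was analysed here. All 12 windows of about 40 neighbouring genes had a median above that of all genes (0.013), from 0.069 to 0.184, and 77.8% of its genes lay above 0, against 52.2% elsewhere. A few genes or a single region are argued against by these 12 windows. KD3 alone is argued against by a median of 0.119 without it, and gene length by 0.107 with the length trend removed. Other chromosomes showed smaller shifts. Medians were 0.07 on chromosome 8 (14 of 14 windows above that of all genes), 0.06 on chromosome 18 (5 of 6 windows) and 0.06 on chromosome 1 (12 of 15 windows), with more genes higher than elsewhere (Fisher's exact test over genes, two-sided, adjusted p = 2.77e-05, 0.0221 and 0.00155). By the same test, fewer genes were higher than elsewhere on chromosomes 3, 9, 15, 17 and 7 (adjusted p = 0.00484, 0.0048, 0.0221, 0.0403 and 0.0418), of which chromosome 15 had the lowest median (-0.04, 0 of 10 windows above that of all genes).

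Of the 10 splits of the 6 libraries into 3 and 3, the real split gave 1823 changed genes, 71 of them by 2-fold or more, where the highest other split gave 0 of either. Each other split mixes libraries of both groups, so the difference between the groups adds to the spread within its sides. Few or no gene calls follow from that by construction, so the 0 does not measure chance. For gene lists, the real split gave 10 and the highest other split 6, in which camera's preset correlation treats members as nearly independent. In each case 1 of the 10 splits, the real one, gave a result as large, and these splits are too few for a share under 0.05.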
